A study of Rattus norvegicus with 176 samples.

How the data were processed

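Total RNA of rat liver sections was hybridized to Affymetrix arrays, 1 array per section, from F344 rats per the labels. The deposited values were intensities on a linear scale for 15922 probe sets, and the labels named MAS5 as the processing tool, without a version, a scaling target or a handling of replicates. Group, time, arm, section tag, rat number and title suffix were read from the labels. The titles named a dose of 5000 ppm CA even for control rats, so the group names and not the dose were used to tell treated from control animals. No 2 arrays held identical values, and the correlation of log2 values between arrays of 1 group was at least 0.935, with a median of 0.972, and at most 0.987 between any 2 arrays.

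Probe sets were given gene symbols through their Entrez identifiers (12748), their accessions (2) or the name on the array (33), so that 12783 had 1 gene, 312 had several and 2827 had none, and 10411 genes had at least 1 probe set. Where a gene had several probe sets, the one with the highest mean log2 value over all arrays stood for it in gene lists and counts of genes. Counts called "probe sets" are over all tested probe sets.

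Array medians ran from 25.35 to 187.2, and their 90th percentile was 2.13 times their 10th, above the limit of 1.5 that had been set. Each array was therefore scaled to the median of the medians, 99.35, so levels and folds are relative to the median probe set, and a change of most genes at once would not be seen. An offset of 25 was added before taking log2, which shrinks folds of dim genes. Probe sets had to exceed the 40th percentile of their own array on at least 3 arrays of a fit. This left 12393 probe sets (8733 genes) for untagged sections, 11566 (8325) for TU against untagged sections, 10174 (7442) for PERI against untagged and 10516 (7679) for TU against PERI sections.

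All untagged sections entered 1 limma fit with a mean per group and 118 residual degrees of freedom, and contrasts of these means answered the questions of the labels. CA was compared with control at 6 times, DEN with control at 6, and DEN-CA with DEN at 5, with differences of these effects between arms, between 18m and 5j and between groups with and without rev. Groups with rev were set against each other, CA rats labelled 18 against controls of 18m, and controls of 18m against those of 5j. In tagged sections the rat number gave the pairing, since sections with the same number came from the same animal. TU sections of 1 rat were averaged on the log2 scale, the untagged section was subtracted, and the differences of 9 CA and 7 DEN-CA rats entered 1 limma fit with 14 residual degrees of freedom. PERI sections of 5 rats were handled in the same way. Within-animal correlation estimated over all sections was -0.027, and 0.132 in the fit of TU and untagged sections. Moderated statistics came from lmFit and eBayes with a trend of variance on intensity, tests were two-sided, and p-values were adjusted after Benjamini and Hochberg over the probe sets of a fit, with 0.05 as the threshold. "Rose" and "fell" are used only for genes past it.

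Gene lists of pathways and cell types, 38 in number, were fixed together with the comparisons, and lists with at least 5 measured genes were tested. They were tested with limma's camera against all other genes with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Most calls ended under it. Each list is also given as counts of its genes past 0.05, adjusted over all probe sets and over the list alone. Genes named in the text followed a fixed rule. For the CA and DEN-CA families these were the 12 highest and 12 lowest mean changes among genes past 0.05 in the same direction at every time and the 4 highest and lowest at each time. For other comparisons they were the 12 highest and lowest, besides a fixed panel of marker genes and up to 4 members of each list with the smallest p-values. Genes of unknown function or with probe sets shared by near-identical family members were left out of the text.

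The code was first tested on known changes in simulated data, not the arrays. Over 10 comparisons, 12% to 38% of changes of 0.5 log2 were called (70% in TU, CA arm). At 1 log2 67% to 90% were called, at 2 log2 94% to 100%. The 70% says little of its arrays, whose calls ran from 1 to 2501 with single rats left out. False calls were 2.65% to 6.87% of calls (10.1% in DEN at 12m). Of 34 lists, 3 were moved and only these called, leaving false list calls in real data untested. Simulated changes of 0.5 log2 were mostly missed in 9 of 10 comparisons.

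Alternatives fixed before the data were examined were offsets of 6 and 99, no scaling, quantile normalization, no filter and a filter at the 70th percentile, the B suffix as a covariate, fits with only the groups of a contrast, array weights, a 2-fold limit besides the adjusted p, all sections with the rat as a random block, tagged sections without pairing, pooled controls, and leaving out each rat in turn. Later additions were a covariate for array brightness or for the upper tail of an array, leaving out 4 arrays with unusual composition, an exchange of 2 sections of rat 4137, and leaving out DEN rev rats 4081 and 4084. Group labels were also exchanged in up to 100 splits per comparison to learn how many calls other groupings of the same rats give. Some of these splits exchange a single pair of rats and so keep much of the contrast. R 4.3.3 with limma 3.58.1 made all tests, and Python 3.11.15 with matplotlib 3.10.9 drew the figures.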

Results

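RNA from liver sections of F344 rats was measured on Affymetrix arrays of 15922 probe sets, in a study of long-term dietary clofibric acid (CA), a fibrate that activates the nuclear receptor PPARalpha. Each animal had 1 section without a tag. A further 23 sections were tagged TU, from 16 of these animals, and 5 were tagged PERI, from 5 of them. The untagged sections fell into 30 groups of 3 to 6 rats. Control, CA, DEN and DEN-CA rats (DEN is the field's abbreviation for the liver carcinogen diethylnitrosamine) were sampled at 5j, 1m, 3m, 9m and 12m, with control and CA rats also at 18m, and 5 rats made up each of these groups. A control and a DEN group of 5 rats carried the time -8 without a unit. Groups tagged rev had 4 CA rats and 3 controls at 18m, and 6 DEN, 5 DEN-CA and 4 control rats at 12m. A further 6 CA rats were labelled 18 without a unit. The labels did not spell out j, rev, TU or PERI, and 46 of the untagged arrays carried a B suffix that they did not explain. Array medians of the deposited intensity lay between 25.35 and 187.2, and each array was scaled to the middle of these medians. Scaled signals below are group means ± SD over rats, and log2 fold changes are given ± their standard error. Genes "passed" with an adjusted p below 0.05 from limma, and counts "over the list alone" are of genes past 0.05 adjusted within their list. Medians of lists are medians of log2 fold changes.

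**Figure D1:**
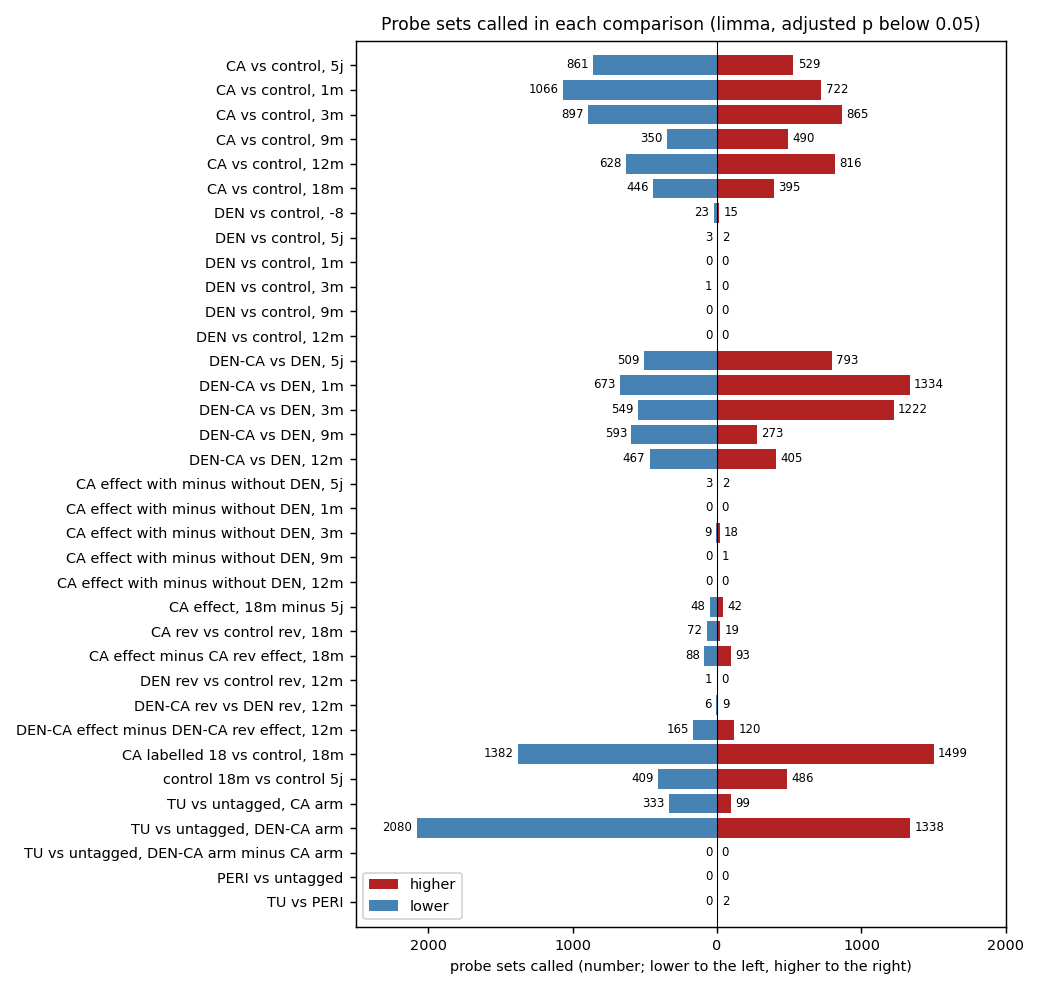
Probe sets called at an adjusted p below 0.05 in each comparison, with those higher drawn to the right and those lower to the left of 0 on a linear axis. Every CA comparison of untagged sections had between 840 and 2007 called probe sets in groups of 5 against 5 rats, and DEN alone had at most 38.

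What CA did to the liver over time was asked by CA against control rats at 6 times, 5 rats in each group. Genes higher under CA at every time numbered 101 and genes lower at every time 75, of 8733 genes tested. Hdc (histidine decarboxylase) rose most on average over the times, with log2 fold changes between 2.93 and 4.54, and stood at 3.57 ± 0.36 at 18m (11.9-fold, adjusted p = 6.5e-15). Acot1, an acyl-CoA thioesterase, rose by 5.62 ± 0.34 at 5j, when its signal was 2230 ± 1690 under CA and 10.9 ± 7.32 in controls. The control signal lay under the offset of 25, which therefore sets the size of this change (6.79 ± 0.45 with an offset of 6, 4.06 ± 0.26 with 99). At 18m Acot1 was still up by 3.06 ± 0.34. Apoa4 (an apolipoprotein) fell by 5.61 ± 0.22 (48.8-fold) at 1m and was lower at every time, from 5450 ± 1150 in controls to 87.3 ± 22.4. The pantetheinase Vnn1, the aquaglyceroporin Aqp3, asparagine synthetase Asns, the nicotinic receptor subunit Chrna2, malic enzyme Me1, the peroxisomal bifunctional enzyme Ehhadh, the carnitine palmitoyltransferase Cpt1b and the desaturase Fads2 were also higher at every time, with means over the times from 2.01 (Fads2) to 3.13 (Vnn1). The ornithine aminotransferase Oat, Cyp4a8, the complement proteases C1s and C1r, Cyp3a9, the bile acid-CoA ligase Slc27a5, the cytokine Il33, the chemokine Cxcl12, the interferon-induced Ifitm3 and Apom were lower at every time, with means from -2.74 (Oat) to -1.47 (Apom). Called probe sets numbered 1390 (529 higher, 861 lower) at 5j, 1788 (722 and 1066) at 1m, 1762 (865 and 897) at 3m, 840 (490 and 350) at 9m, 1444 (816 and 628) at 12m and 841 (395 and 446) at 18m. After quantile normalization the 5j split was 875 higher and 937 lower. In the CA group of 12m the untagged section of rat 4137 stood apart, with signals of 135 for Hdc (others 875 to 1380), 30.3 for Acot1 (109 to 329) and 3970 for Scd2 (731 to 1930). Without this rat the changes at 12m were 3.51 ± 0.35 for Hdc (with it 2.93 ± 0.36), 2.39 ± 0.34 for Acot1 (1.98 ± 0.34) and 4.33 ± 0.33 for Scd2 (4.69 ± 0.32). Within the arrays with the B suffix and within those without it, 487 and 278 probe sets were called at 5j, 203 and 1175 at 1m, 404 and 1284 at 3m, and 58 and 565 at 9m. The subsets without it at 5j (3 CA and 1 control) and with it at 1m and 3m (1 and 2) and 9m (1 and 1) had arms of a lone array, assumed to vary like the other groups. The fold changes of these subsets had an r across all probe sets, which are not independent replicates, of 0.57, 0.54, 0.54 and 0.52 at these times.

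**Figure D2:**
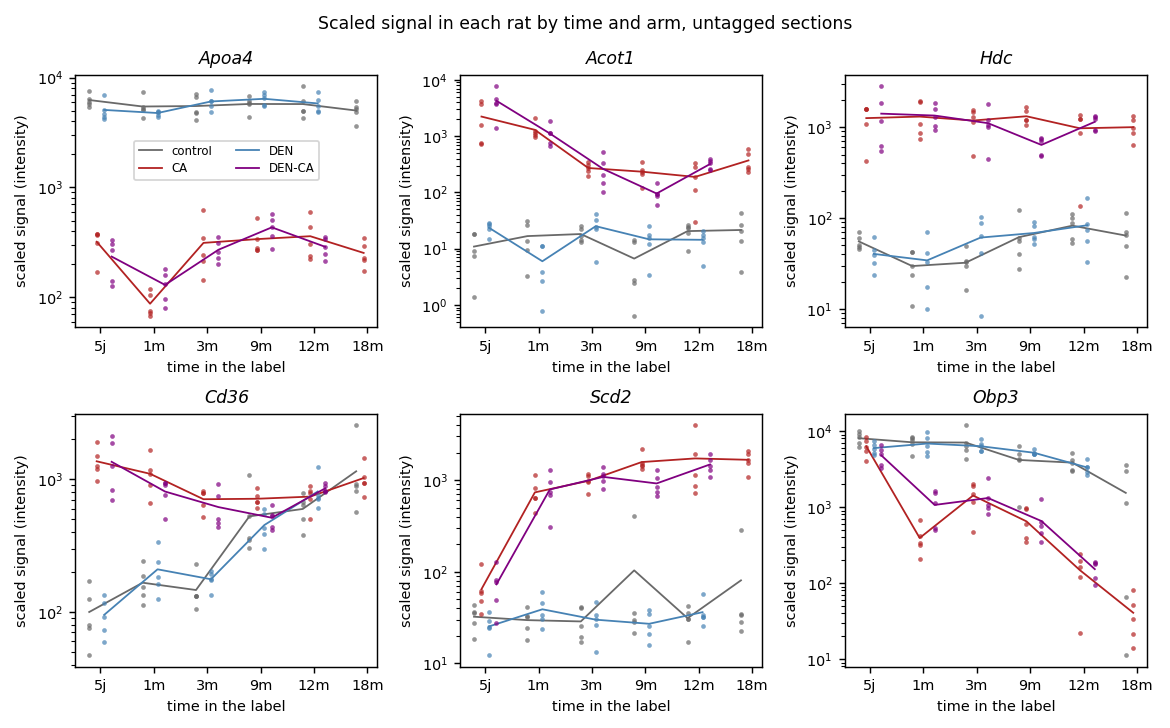
Scaled signal of 6 genes on a log axis in each rat (points) at each time, with lines through the group means, for control, CA, DEN and DEN-CA rats (untagged sections, 5 rats per group). Apoa4 stayed at 87.3 to 360 under CA at all times, and Scd2 rose from 1m on.

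Many genes of fatty acid oxidation and other targets of PPARalpha rose at 5j. At 5j, of 20 mitochondrial fatty acid oxidation genes, 15 rose, 0 fell and 5 did not pass (16 over the list alone, camera adjusted p = 4.6e-22, 0.0076 with estimated correlation). Cpt1b (2.39 ± 0.20), Decr1 (1.19 ± 0.13), Eci1 (1.49 ± 0.19, with 0.18 in another probe set not past) and Hadha (1.10 ± 0.15) had the smallest p-values in it. At 5j, of 29 genes of the list of other PPARalpha targets in lipid handling, 16 rose, 1 fell and 12 did not pass (18 over the list alone, camera adjusted p = 1.3e-23, 0.00028 with estimated correlation). Acot1, Cd36 (3.53 ± 0.31), Me1 (2.22 ± 0.20) and Vnn1 (3.56 ± 0.36) led that list, and its member Cyp4a8 fell against the list. At 5j, of 27 peroxisomal beta-oxidation and peroxisome genes, 12 rose, 0 fell and 15 did not pass (13 over the list alone, camera adjusted p = 4e-10, 0.15 with estimated correlation). Ehhadh (2.64 ± 0.22), Acot8 (1.92 ± 0.22), Ech1 (1.07 ± 0.17) and Acot12 (1.06 ± 0.19) led here. At 18m, of 20 mitochondrial fatty acid oxidation genes, 6 rose, 0 fell and 14 did not pass (6 over the list alone, camera adjusted p = 2.9e-06, 0.43 with estimated correlation). The other PPARalpha targets had 11 of 29 higher and 2 lower at 18m (camera adjusted p = 1.5e-05, 0.38 with estimated correlation). The peroxisomal list then had 7 higher and 1 lower (camera adjusted p = 0.00049, 0.51 with estimated correlation). Over the 6 times 5 to 15 mitochondrial, 9 to 16 other target and 4 to 12 peroxisomal genes rose. At 12m the median of the peroxisomal list less that of all genes was 0.14, and 0 after quantile normalization. Among fatty acid synthesis genes, 1 to 8 of 15 rose at a time, 8 of them at 12m (camera adjusted p = 0.00064, 0.37 with estimated correlation). The stearoyl-CoA desaturase Scd2 (4.69 ± 0.32), Srebf1 (2.08 ± 0.32), Fasn (1.63 ± 0.31) and Acly (0.75 ± 0.20) had the smallest p-values there. In the unfolded protein response list Asns (2.69 ± 0.25), Atf4 (0.71 ± 0.17), Trib3 (1.86 ± 0.48) and Ddit3 (0.46 ± 0.14) rose at 18m. At 18m, of 22 unfolded protein response genes, 4 rose, 0 fell and 18 did not pass (5 over the list alone, camera adjusted p = 0.031, 0.54 with estimated correlation).

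Part of the genes of the apolipoprotein, complement, bile acid, macrophage and interferon lists fell under CA, and none of the camera calls given for these lists held with an estimated correlation. At 1m, of 14 apolipoproteins and lipoprotein enzymes, 0 rose, 8 fell and 6 did not pass (8 over the list alone, camera adjusted p = 5.8e-10, 0.13 with estimated correlation). Apoa4, Apom (-1.61 ± 0.20), Lcat (-0.95 ± 0.14) and Apoc3 (-1.07 ± 0.18) had the smallest p-values at 1m. Over the 6 times 4 to 8 of these genes fell. At 18m, of 21 coagulation and complement genes, 0 rose, 8 fell and 13 did not pass (12 over the list alone, camera adjusted p = 5.2e-11, 0.38 with estimated correlation). C1s (-2.18 ± 0.21), C1r (-1.72 ± 0.20), Mbl2 (-0.62 ± 0.13) and Mbl1 (-0.72 ± 0.15) led, and 6 to 10 genes of that list fell at a time. At 5j, of 16 bile acid synthesis and transport genes, 0 rose, 7 fell and 9 did not pass (7 over the list alone, camera adjusted p = 0.0018, 0.43 with estimated correlation). Slc27a5 (-1.56 ± 0.21), Cyp8b1 (-0.93 ± 0.20), Slco1b2 (-0.78 ± 0.17) and Cyp7a1 (-1.47 ± 0.32) were foremost. Cyp7a1, the first enzyme of bile acid synthesis, rose at 3m instead, by 1.11 ± 0.32. At 1m, of 15 macrophage and Kupffer cell markers, 0 rose, 9 fell and 6 did not pass (9 over the list alone, camera adjusted p = 4.3e-05, 0.3 with estimated correlation). Lyz2 (-0.91 ± 0.16), Ctss (-0.90 ± 0.20), C1qa (-0.78 ± 0.20) and Clec4f (-0.85 ± 0.24) led it, and 0 to 9 of its genes fell at a time. At 1m, of 22 interferon response and antigen presentation genes, 0 rose, 8 fell and 14 did not pass (9 over the list alone, camera adjusted p = 0.00075, 0.21 with estimated correlation). Ifitm3 (-1.54 ± 0.21), Irf1 (-0.99 ± 0.17), Ifitm1 (-1.01 ± 0.20) and Psmb8 (-0.96 ± 0.20) had its smallest p-values. At 1m, of 12 periportal hepatocyte genes, 0 rose, 6 fell and 6 did not pass (6 over the list alone, camera adjusted p = 0.00075, 0.32 with estimated correlation). Over the times 1 to 6 of these fell. At 1m, of 20 stellate cell and fibroblast markers, 0 rose, 10 fell and 10 did not pass (10 over the list alone, camera adjusted p = 0.00014, 0.092 with estimated correlation). Timp1 (-0.84 ± 0.20) and Col3a1 (-0.72 ± 0.18) were among them. In the growth hormone and sex dependent list Obp3, a lipocalin, fell by 4.17 ± 0.66 at 1m, from 7110 ± 1490 to 392 ± 179. At 12m it stood at -4.66 ± 0.66. At 1m, of 17 growth hormone and sex dependent liver genes, 0 rose, 6 fell and 11 did not pass (7 over the list alone, camera adjusted p = 0.032, 0.38 with estimated correlation). Cell cycle genes passed in small numbers (0 of 33 rose and 0 to 3 fell at a time). Gstp1, a marker of preneoplastic foci, was at -0.39 ± 0.23 at 18m (adjusted p = 0.38).

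**Figure D3:**
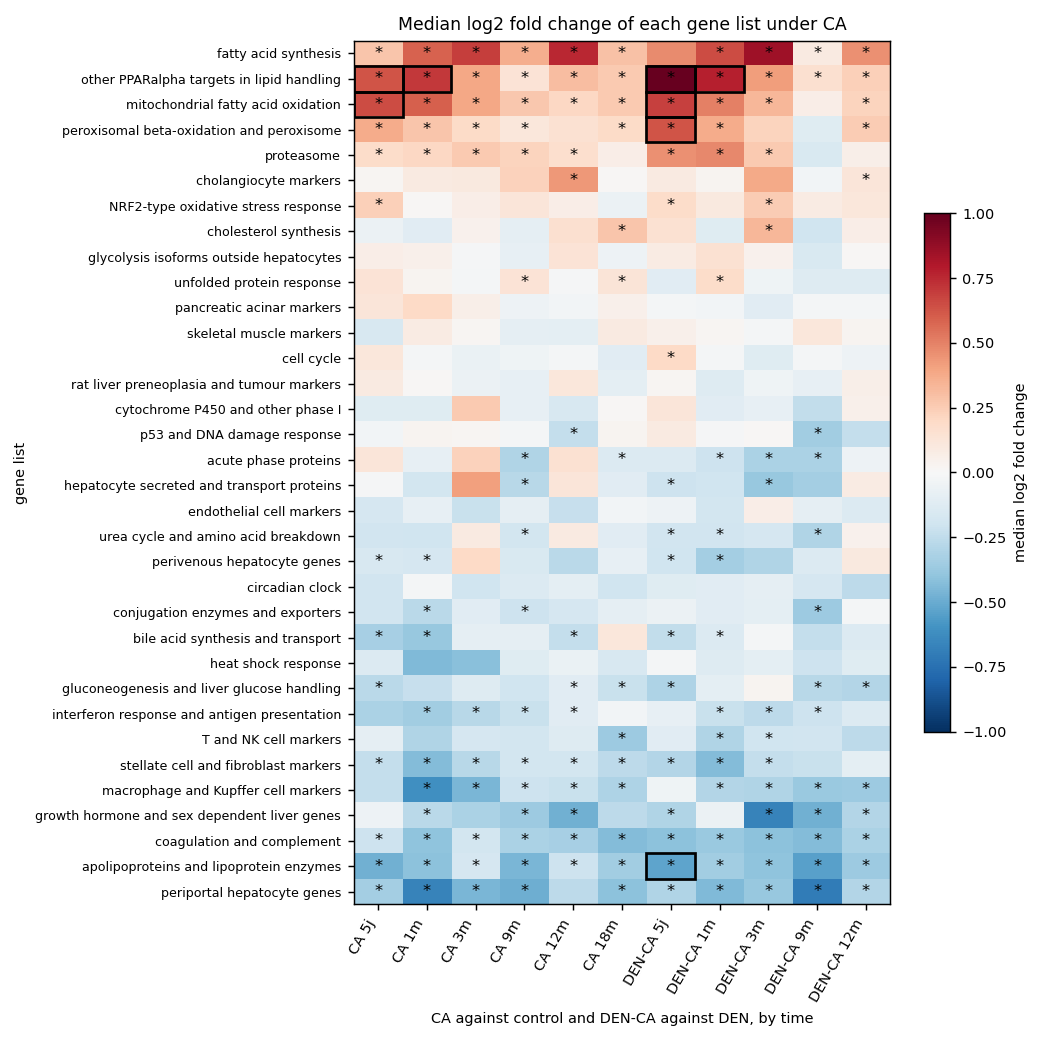
Median log2 fold change of each gene list (colour) under CA against control and DEN-CA against DEN at each time, with asterisks for a camera adjusted p below 0.05 and frames where it held with an estimated correlation. Frames marked 3 medians under CA and 5 under DEN-CA, all at 5j and 1m.

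The CA effects at 18m and 5j were compared as a difference of differences in 20 rats. Scd2 gained 3.82 ± 0.46 (14.2-fold, adjusted p = 9.2e-10), with 32.2 ± 9.53 in controls and 64.6 ± 33.3 under CA at 5j and 80.5 ± 113 and 1670 ± 393 at 18m. Cela1, an elastase, gained 3.00 ± 0.46, since its signal under CA was 757 ± 196 at 5j and 802 ± 203 at 18m while controls went from 526 ± 118 to 64.7 ± 64.9. The effect on the fatty acid transporter Cd36 fell by 3.52 ± 0.44, from 3.53 ± 0.31 at 5j to 0.00 ± 0.31 at 18m. Signals were 736 to 1910 under CA, and in controls 47.2 to 172 (5j) and 567 to 2550 (18m). The effect on Acot1 (-2.56 ± 0.48), Aldh1a1 (-2.72 ± 0.42, up in controls), Cyp4a8 (-2.48 ± 0.30), Hmox1 (-1.49 ± 0.30) and Angptl4 (-1.40 ± 0.35) was also lower at 18m. That on Cyp1a2 (2.02 ± 0.36) and Cyp7a1 (1.76 ± 0.46) was higher. In all, 90 probe sets passed (42 higher, 48 lower). Of 29 other PPARalpha targets in lipid handling, 0 were higher, 5 lower and 24 did not pass (9 over the list alone, camera adjusted p = 2e-12, 0.034 with estimated correlation). Of 20 mitochondrial fatty acid oxidation genes, 0 were higher, 1 lower and 19 did not pass (4 over the list alone, camera adjusted p = 3.8e-08, 0.36 with estimated correlation). None of 27 peroxisomal beta-oxidation and peroxisome genes passed (median -0.35, 3 over the list alone, camera adjusted p = 0.0025, 0.83 with estimated correlation). Of 16 NRF2-type oxidative stress response genes, 0 were higher, 2 lower and 14 did not pass (4 over the list alone, camera adjusted p = 2.1e-05, 0.28 with estimated correlation). Of 16 bile acid synthesis and transport genes, 1 was higher, 0 lower and 15 did not pass (3 over the list alone, camera adjusted p = 0.00048, 0.65 with estimated correlation). The B suffix, on 4 of 5 control arrays of 5j and no array of 18m, was largely confounded with this difference.

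DEN against control rats, 5 in each group, asked what the carcinogen alone left in the liver. At -8 the p53 targets Ccng1 (1.29 ± 0.15, 2.44-fold, adjusted p = 1.4e-11), Cdkn1a (1.01 ± 0.23) and Mdm2 (0.95 ± 0.23, with 0.79 in another probe set not past) and the DNA repair gene Mgmt (1.36 ± 0.17) rose, and Aldh1a1 rose most, by 2.86 ± 0.29. Ccng1 stood at 515 ± 97.4 against 196 ± 39.8, and at 269 ± 48.6 against 220 ± 50.6 at 5j (0.27 ± 0.15, adjusted p = 0.62). The DNA end-joining factor Nhej1 (1.47 ± 0.16) and Ephx1 (0.99 ± 0.14) also rose, and Larp1 (-1.09 ± 0.23, with 3 other probe sets at -0.30 to -0.20 not past), Il6st (-0.80 ± 0.19, with -0.75 and -0.50 in 2 others not past) and Slc12a2 (-0.79 ± 0.16) were among those that fell. At -8, of 16 p53 and DNA damage response genes, 4 rose, 0 fell and 12 did not pass (5 over the list alone, camera adjusted p = 1.7e-09, 0.0011 with estimated correlation). Of 38 probe sets called at -8, 15 were higher and 23 lower, against 24 higher and 13 lower after quantile normalization. The count went from 14 without DEN rat 4051 to 115 without DEN rat 4050 (24 without control 4003, 20 without control 4004 and 24 without DEN 4048). Within the 4 DEN and 5 control arrays with the B suffix 32 were called, and no control lacked it. Later, 5 probe sets passed at 5j (3 without control 4007, DEN 4053 or DEN 4057), where Nhej1 was still up by 0.73 ± 0.16 and Cd14 fell by 1.30 ± 0.22. At 3m 1 passed (2 to 10 without controls 4017, 4018 or 4020 or DEN rats 4063, 4065 or 4067). None passed in limma at 1m, 9m or 12m, where 548, 458 and 332 probe sets had an unadjusted p below 0.05 (2 passed at 1m without DEN rat 4060 or 4062). At 12m, none of 8 pancreatic acinar markers passed, with a median of -0.21 (1 over the list alone, camera adjusted p = 0.00072, 0.0068 with estimated correlation). The cell cycle list at 5j had none of its 33 genes past, with a median of 0.19 (camera adjusted p = 7.3e-05, 0.65 with estimated correlation). Gstp1 lay between -0.37 (-8) and 0.17 (12m) and never passed.

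CA on top of DEN was compared with DEN alone at 5 times, 5 rats in each group, to ask whether the drug acted alike after DEN. Genes higher at every time numbered 81 and lower 68 of 8733. Hdc averaged 3.78 over the times (3.53 ± 0.36, 11.6-fold at 12m, adjusted p = 1.1e-14). Acot1 rose by 6.27 ± 0.34 at 5j (6.99 ± 0.45 with an offset of 6, 4.96 ± 0.26 with 99) and by 3.12 ± 0.34 at 12m. Vnn1, Aqp3, the serine synthesis enzyme Phgdh, Asns, Me1, Cidea, Cpt1b, Fads2, Ehhadh and Acsl3 were also higher at every time. Apoa4 (mean -4.36), Oat (-2.55), Nrep (-2.19), Cyp4a8 (-2.18), C1s (-1.97) and C1r (-1.56) were lower. Scd2 rose by 3.57 ± 0.32 at 1m and 4.62 ± 0.32 at 12m, from 36.1 ± 12.3 to 1480 ± 332, and Obp3 fell by 4.25 ± 0.66 at 12m. Called probe sets numbered 1302 (793 higher, 509 lower) at 5j, 2007 (1334 and 673) at 1m, 1771 (1222 and 549) at 3m, 866 (273 and 593) at 9m and 872 (405 and 467) at 12m. After quantile normalization they were 1289 and 1070 at 1m, 1187 and 919 at 3m, and 583 and 511 at 9m. With the B suffix as a covariate 1670 passed at 9m, where 4 of 5 DEN-CA and 1 of 5 DEN arrays carried it. At 5j, of 29 other PPARalpha targets in lipid handling, 20 rose, 1 fell and 8 did not pass (22 over the list alone, camera adjusted p = 1.9e-33, 5.8e-06 with estimated correlation). At 5j, of 20 mitochondrial fatty acid oxidation genes, 17 rose, 0 fell and 3 did not pass (18 over the list alone, camera adjusted p = 6.2e-25, 0.0033 with estimated correlation). At 5j, of 27 peroxisomal beta-oxidation and peroxisome genes, 14 rose, 0 fell and 13 did not pass (17 over the list alone, camera adjusted p = 7.1e-15, 0.024 with estimated correlation). At 5j, of 14 apolipoproteins and lipoprotein enzymes, 0 rose, 9 fell and 5 did not pass (9 over the list alone, camera adjusted p = 6.9e-15, 0.024 with estimated correlation). At 5j, of 27 proteasome genes, 15 rose, 0 fell and 12 did not pass (21 over the list alone, camera adjusted p = 8.4e-11, 0.22 with estimated correlation). At 3m, of 17 growth hormone and sex dependent liver genes, 0 rose, 5 fell and 12 did not pass (6 over the list alone, camera adjusted p = 0.00022, 0.11 with estimated correlation). Of 20 stellate cell and fibroblast markers, 2 fell at 5j, 6 at 1m and 3 at 3m (camera adjusted p = 0.00014, 1.4e-05 and 0.00022, and 0.055, 0.051 and 0.11 with estimated correlation). Of 15 macrophage and Kupffer cell markers 1 fell at 3m (camera adjusted p = 0.00059, 0.44 with estimated correlation). Calls within arrays with and within those without the B suffix were 435 and 838 at 5j, 1562 and 131 at 1m, 695 and 137 at 3m, and 137 and 221 at 9m, with an r between their fold changes across all probe sets of 0.6, 0.47, 0.58 and 0.45. Lone arrays, assumed to vary like the other groups, made up an arm without it at 1m (1 DEN-CA and 2 DEN), 3m (1 and 3) and 9m (1 and 4) and with it at 9m (4 and 1). The fold changes of both arms, which shared no rats, had Pearson's r across 8733 genes of 0.684 at 5j, 0.733 at 1m, 0.662 at 3m, 0.701 at 9m and 0.761 at 12m. Neither genes nor probe sets are independent replicates. At 12m 237 genes were called higher and 202 lower in both arms, where independent lists would share 22.8 and 16.8.

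Whether DEN altered the CA effect was tested at each time as a difference of differences over 20 rats. At 3m Ssh2, a cofilin phosphatase, had a CA effect 1.38 ± 0.26 higher with DEN (2.6-fold, adjusted p = 0.0045). Chn1 (1.16 ± 0.26) and Mink1 (1.06 ± 0.23) were also higher, and the interferon receptor Ifnar1 (-0.86 ± 0.20 in 1 of 3 probe sets, -0.28 and -0.08 in the others, not past), the cargo receptor Lman1 (-1.12 ± 0.26), Mug1 (-1.34 ± 0.32) and Cand2 (-1.55 ± 0.35) lower. Of 27 probe sets called at 3m, 18 were higher and 9 lower. The count was 2 without control 4016 or CA 4129, 4 to 12 without 4018, 4063, 4064, 4067, 4095, 4096, 4097, 4099, 4127 or 4130, 42 or 43 without 4017, 4066 or 4131, and 225 without CA 4128. The B suffix was on 4 of 5 DEN-CA, 2 DEN, 1 CA and 2 control arrays of 3m, and 2 probe sets passed with it as a covariate, with a median absolute change of the 27 of 0.97 against 1.06 and all signs kept. At 3m, none of 18 acute phase proteins passed, with a median of -0.57 (10 over the list alone, camera adjusted p = 9e-11, 0.26 with estimated correlation). Its median less that of all genes went from -0.66 to 0 with quantile normalization. At 3m, none of 15 hepatocyte secreted and transport proteins passed, with a median of -0.4 (6 over the list alone, camera adjusted p = 1.5e-06, 0.26 with estimated correlation). There the same value went from -0.49 to 0.03. At 3m, none of 14 apolipoproteins and lipoprotein enzymes passed, with a median of -0.37 (4 over the list alone, camera adjusted p = 1.3e-05, 0.57 with estimated correlation). At 3m, none of 18 cholesterol synthesis genes passed, with a median of 0.41 (1 over the list alone, camera adjusted p = 0.011, 0.75 with estimated correlation). At 5j 5 probe sets passed, Stat5b among them (-1.12 ± 0.25). None passed in limma without control 4006, DEN 4054, DEN-CA 4086 or CA 4117 or 4119, 1 or 2 passed without 4007, 4008, 4053, 4057, 4087 or 4120, and 10 to 29 without 4010, 4055, 4056, 4088, 4089, 4118 or 4121. At 5j, none of 27 proteasome genes passed, with a median of 0.28 (0 over the list alone, camera adjusted p = 0.00025, 0.87 with estimated correlation). At 9m 1 passed (0 without 4023, 4027, 4072, 4115, 4132 or 4135). None passed in limma at 1m or 12m, where 1130 and 454 had an unadjusted p below 0.05 (1 passed at 12m without 4139). A share of 0.05 of the 12393 tested lies between 454 and 1130. At 9m, none of 27 proteasome genes passed, with a median of -0.38 (3 over the list alone, camera adjusted p = 7.1e-08, 1 with estimated correlation). At 12m, none of 29 other PPARalpha targets in lipid handling passed, with a median of 0.31 (0 over the list alone, camera adjusted p = 0.0027, 0.99 with estimated correlation). For Acot1 the difference was 0.65 ± 0.48 at 5j, -1.39 ± 0.48 at 9m and 1.15 ± 0.48 at 12m. It was -1.21 ± 0.50 for Hdc at 9m and 0.15 ± 0.31 for Ehhadh at 5j. None of the 5 passed, so gaps of over 2-fold in Acot1 and Hdc were neither shown nor excluded. The 12m differences include CA rat 4137, without which the CA effect on Acot1 was 2.39 instead of 1.98.

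Groups tagged rev at 18m, 4 CA and 3 control rats, were compared with each other and with the CA effect of the untagged 18m groups. Apoa4, the strongest fall under CA, stood at 5660 ± 385 in CA rev and 5340 ± 1770 in control rev rats, against 253 ± 69.1 in CA rats of 18m. Acot1 stood at 21.6 ± 9.71 against 33.1 ± 9.24. Of the 101 genes higher under CA at every time 3 were called higher in the rev groups, with a median log2 fold change of 0.09, and of the 75 lower genes 1 was called lower and 1 higher, with a median of 0.02. Chrna2 (1.64 ± 0.38), Fads2 (1.08 ± 0.29) and Nipal2 (1.06 ± 0.17) rose, and Sult2a2 most, by 3.12 ± 0.69 (8.67-fold, adjusted p = 0.0076). With only the rev groups of 18m in the fit no probe set passed in limma, and 782 had an unadjusted p below 0.05. Of the T and NK cell markers Prf1 (perforin, -2.16 ± 0.51), Nkg7 (-1.97 ± 0.46), Klrb1a (-1.66 ± 0.39) and Spn (-1.72 ± 0.37) fell. Without control rev rat 4043 they stood at -0.94 ± 0.54, -0.79 ± 0.48, -0.45 ± 0.39 and -0.72 ± 0.37, none past 0.05. The 4 measured erythroid markers also had their highest mean log2 signal in 4043, at 10.55 (8.89 to 9.31 in the other rats). Of 16 T and NK cell markers, 0 rose, 4 fell and 12 did not pass (11 over the list alone, camera adjusted p = 6.3e-12, 0.034 with estimated correlation). Of 33 cell cycle genes, 0 rose, 2 fell and 31 did not pass (11 over the list alone, camera adjusted p = 6.3e-12, 0.034 with estimated correlation). Mcm6 (-1.26 ± 0.32) and Cdkn3 (-1.26 ± 0.33) passed. Of 15 macrophage and Kupffer cell markers, 0 rose, 1 fell and 14 did not pass (7 over the list alone, camera adjusted p = 1.3e-08, 0.21 with estimated correlation). None of 18 cholesterol synthesis genes passed, with a median of 0.34 (0 over the list alone, camera adjusted p = 3.7e-05, 0.52 with estimated correlation). Of 91 probe sets 19 were higher and 72 lower, 54 and 88 after quantile normalization. The count fell to 7 without control rev rat 4043, the highest of the 7 rats in 69 of the 72 lower probe sets. It was 272 without control rev 4044 and 217 without 4046 (36 to 47 without CA rev 4148, 4149 or 4151). At 18m the CA effect exceeded the rev effect for Scd2 by 3.98 ± 0.50, Vnn1 by 3.66 ± 0.57, Acot1 by 3.39 ± 0.53 and Aqp3 by 3.26 ± 0.38, and was lower for Apoa4 (-4.33 ± 0.34), Oat (-2.77 ± 0.51) and Cxcl12 (-1.92 ± 0.27). In that difference 181 probe sets passed (93 higher, 88 lower), 88 without 4043, 293 without 4044, 116 without control 4038 and 277 without control 4040. Of 14 apolipoproteins and lipoprotein enzymes, 0 were higher, 2 lower and 12 did not pass (5 over the list alone, camera adjusted p = 6.4e-09, 0.29 with estimated correlation). Of 21 coagulation and complement genes, 0 were higher, 3 lower and 18 did not pass (7 over the list alone, camera adjusted p = 3.9e-07, 0.29 with estimated correlation). Of 29 other PPARalpha targets in lipid handling, 7 were higher, 1 lower and 21 did not pass (10 over the list alone, camera adjusted p = 0.021, 0.59 with estimated correlation).

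In the rev groups of 12m, 6 DEN rats were compared with 4 controls and 5 DEN-CA rats with the DEN rats. DEN rev against control rev gave 1 probe set (3 without DEN rev 4078, 2 without 4032, 4082 or 4083, 0 without 4034 or 4080). None of 17 growth hormone and sex dependent liver genes passed, with a median of -0.36 (11 over the list alone, camera adjusted p = 0.00021, 0.35 with estimated correlation). In DEN rev rats 4081 and 4084 Obp3 of this list had a log2 signal of 5.77 and 5.32, against 11.2 to 12.71 in the other 4 and 11.39 to 11.76 in control rev rats. Without these 2 rats the median of the list was -0.14 (camera adjusted p = 0.51), and 1 probe set passed. None of 25 cytochrome P450 and other phase I genes passed, with a median of -0.25 (5 over the list alone, camera adjusted p = 1.9e-06, 0.52 with estimated correlation). None of 15 macrophage and Kupffer cell markers passed, with a median of 0.3 (0 over the list alone, camera adjusted p = 0.00027, 0.52 with estimated correlation). Without 4081 and 4084 the P450 (camera adjusted p = 0.11) and macrophage lists (camera adjusted p = 0.13) were not past 0.05 either. In DEN-CA rev against DEN rev Cela1 rose by 2.38 ± 0.31 (5.22-fold, adjusted p = 1.9e-08), to 353 ± 155 against 52.3 ± 40.8, and Chrna2 by 2.23 ± 0.30, Nipal2 by 1.02 ± 0.13 and Col4a5 by 0.85 ± 0.15. Acot2 (-1.35 ± 0.28), Tpd52l1 (-1.07 ± 0.19) and Cyp4a8 (-1.04 ± 0.20, with -0.89 in another probe set not past) fell, and Acot2 was not past 0.05 without 4081 and 4084 (-0.99 ± 0.30). In all 15 probe sets passed (9 higher, 6 lower), and 4 of the 101 genes higher under CA at every time were called higher, against 98 in DEN-CA against DEN at 12m. None of 17 growth hormone and sex dependent liver genes passed, with a median of 1.19 (13 over the list alone, camera adjusted p = 0.00017, 0.22 with estimated correlation). Without 4081 and 4084 the median of this list was 0.01 (camera adjusted p = 0.71), and 11 probe sets passed. None of 12 periportal hepatocyte genes passed, with a median of -0.19 (2 over the list alone, camera adjusted p = 0.00017, 0.76 with estimated correlation). The DEN-CA effect at 12m exceeded the rev effect for Acot1 by 3.64 ± 0.47, Hdc by 3.52 ± 0.49 and Scd2 by 3.50 ± 0.45, and was lower for Obp3 (-5.68 ± 0.92, 51.3-fold), Apoa4 (-4.24 ± 0.30), Nrep (-4.07 ± 0.65), Cish (-3.86 ± 0.87) and Socs2 (-2.87 ± 0.75). Without 4081 and 4084 these differences were -3.57 ± 0.76 for Obp3, -4.35 ± 0.32 for Apoa4, -3.32 ± 0.66 for Nrep, -4.34 ± 0.92 for Cish and -3.22 ± 0.79 for Socs2. Cish and Socs2 are targets of growth hormone signalling through STAT5. Of 285 probe sets 120 were higher and 165 lower, and 297 and 267 after quantile normalization. Of 29 other PPARalpha targets in lipid handling, 9 were higher, 2 lower and 18 did not pass (13 over the list alone, camera adjusted p = 1.1e-09, 0.059 with estimated correlation). Of 17 growth hormone and sex dependent liver genes, 0 were higher, 5 lower and 12 did not pass (6 over the list alone, camera adjusted p = 2.3e-06, 0.058 with estimated correlation). Without 4081 and 4084 its median was -0.23 (camera adjusted p = 0.0011), and 244 probe sets passed. Of 20 mitochondrial fatty acid oxidation genes, 2 were higher, 0 lower and 18 did not pass (6 over the list alone, camera adjusted p = 5.1e-05, 0.37 with estimated correlation).

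The 6 CA rats labelled 18 were compared with the 5 control rats of 18m. Scd2 (4.24 ± 0.31, 18.9-fold, adjusted p = 1.8e-23), Hdc (4.20 ± 0.34), Cela1 (3.78 ± 0.31) and Acot1 (3.71 ± 0.32) rose, and Cyp4a8 (-3.65 ± 0.20), Obp3 (-3.64 ± 0.63), Apoa4 (-2.84 ± 0.21), the male-specific Cyp2c11 (-2.63 ± 0.59) and the retinoid receptor Rxra (-1.85 ± 0.19) fell. Apoa4 stood at 689 ± 187 against 5010 ± 901 in controls. Called probe sets numbered 2881 (1499 higher, 1382 lower). Of 20 mitochondrial fatty acid oxidation genes, 14 rose, 1 fell and 5 did not pass (15 over the list alone, camera adjusted p = 2.2e-05, 0.77 with estimated correlation). Cpt1b (2.20 ± 0.20) and Eci1 (1.27 ± 0.18, with 0.18 in another probe set not past) led. Of 27 peroxisomal beta-oxidation and peroxisome genes, 13 rose, 3 fell and 11 did not pass (21 over the list alone, camera adjusted p = 0.0018, 0.77 with estimated correlation). Ehhadh (1.73 ± 0.21) and Acot8 (1.21 ± 0.21) were higher and Amacr (-1.04 ± 0.19) lower. Of 27 proteasome genes, 12 rose, 0 fell and 15 did not pass (17 over the list alone, camera adjusted p = 0.00099, 0.8 with estimated correlation). Of 12 gluconeogenesis and liver glucose handling genes, 0 rose, 6 fell and 6 did not pass (6 over the list alone, camera adjusted p = 0.022, 0.77 with estimated correlation).

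Ageing without treatment was followed by control rats of 18m against those of 5j, 5 in each group. Prlr, the prolactin receptor, rose by 3.34 ± 0.47 (10.1-fold, adjusted p = 1.1e-07), Cd36 by 3.12 ± 0.31, Igfbp2 by 2.45 ± 0.49, Gsta3 by 2.34 ± 0.31 and Aldh1a1 by 2.31 ± 0.29. Obp3 (-3.92 ± 0.66), the estrogen sulfotransferase Sult1e1 (-3.36 ± 0.62), Cela1 (-2.91 ± 0.33), Cyp3a2 (-2.41 ± 0.63) and Cyp2c11 (-1.92 ± 0.62) fell. Called probe sets numbered 895 (486 higher, 409 lower), 514 without 18m rat 4040, whose Obp3 signal was 11.3, and 550 without 5j rat 4008. The log2 signal of Obp3 was 5.18 in 4040 and 6.51 in 18m rat 4036. It was 10.18 to 11.8 in the other 18m controls and 12.59 to 13.29 at 5j. Of 17 growth hormone and sex dependent liver genes, 1 rose, 8 fell and 8 did not pass (12 over the list alone, camera adjusted p = 0.00028, 0.4 with estimated correlation). Of 25 cytochrome P450 and other phase I genes, 3 rose, 8 fell and 14 did not pass (19 over the list alone, camera adjusted p = 0.00038, 0.42 with estimated correlation). Of 27 peroxisomal beta-oxidation and peroxisome genes, 0 rose, 7 fell and 20 did not pass (10 over the list alone, camera adjusted p = 8.4e-05, 0.4 with estimated correlation). Of 18 cholesterol synthesis genes, 4 rose, 0 fell and 14 did not pass (8 over the list alone, camera adjusted p = 8.4e-05, 0.4 with estimated correlation). None of 15 macrophage and Kupffer cell markers passed, with a median of 0.35 (2 over the list alone, camera adjusted p = 0.00059, 0.42 with estimated correlation). Of 15 hepatocyte secreted and transport proteins, 2 rose, 3 fell and 10 did not pass (10 over the list alone, camera adjusted p = 0.017, 0.42 with estimated correlation). It had a median of -0.43, a mean of 0 and a median less that of all genes that went from -0.41 to 0 with quantile normalization. Since 4 of the 5 arrays of 5j and none of 18m carried the B suffix, age and suffix were largely confounded.

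**Figure D4:**
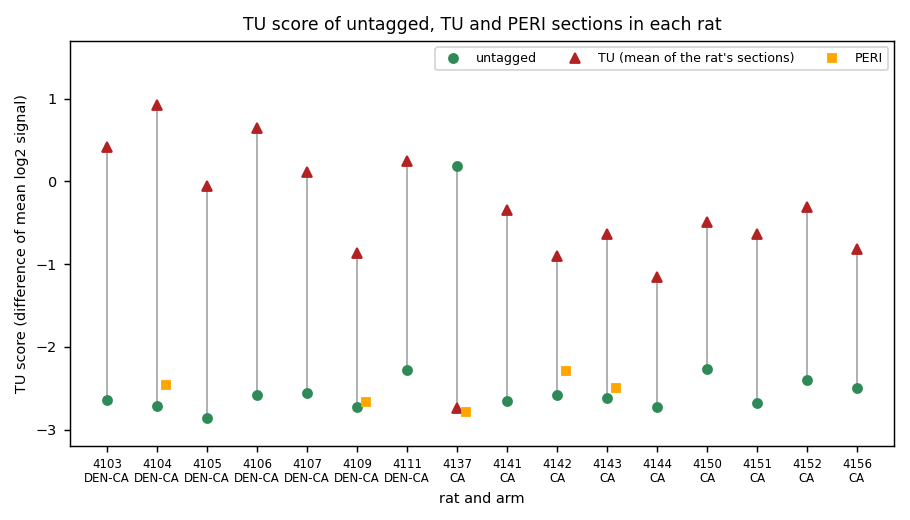
TU score of each section, the mean log2 signal of 138 genes higher minus that of 238 genes lower by over 2-fold in TU of the DEN-CA arm, with lines joining sections of 1 rat. In the CA arm, whose rats did not serve to choose these genes, the TU section scored above the untagged section in 8 of 9 rats. The untagged section of CA rat 4137 scored 0.19 against -2.72 to -2.27 in the other CA rats.

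How TU sections differed from untagged sections of the same rat was tested in 7 DEN-CA rats, rev rat 4111 among them, with 8 TU sections. Slc25a4, a mitochondrial ADP/ATP carrier, rose by 3.78 ± 0.70 (13.7-fold, adjusted p = 0.00083), the macrophage metalloelastase Mmp12 by 3.11 ± 0.62, Bex3 by 3.34 ± 0.63, Nt5dc2 by 3.06 ± 0.51 and the cell cycle inhibitor Cdkn2a by 2.31 ± 0.35. Cyp1a2 (-3.27 ± 0.48, 9.66-fold), Cyp2c7 (-3.01 ± 0.54), the glucose transporter Slc2a2 (-2.64 ± 0.43), Slc27a5 (-2.62 ± 0.35), Oat (-2.40 ± 0.40) and Cyp2c11 (-2.38 ± 0.35) fell. Ehhadh (-0.83 ± 0.17) and Cyp4a1 (-1.63 ± 0.30) fell, and Ccng1 (0.59 ± 0.15) and Cdk1 (0.62 ± 0.22) rose. Called probe sets numbered 3418 (1338 higher, 2080 lower), and 1814 and 1842 after quantile normalization. Of 25 cytochrome P450 and other phase I genes, 1 was higher, 21 lower and 3 did not pass (22 over the list alone, camera adjusted p = 4.6e-09, 0.37 with estimated correlation). Of 16 bile acid synthesis and transport genes, 0 were higher, 14 lower and 2 did not pass (15 over the list alone, camera adjusted p = 8.2e-09, 0.37 with estimated correlation). Of 16 growth hormone and sex dependent liver genes, 1 was higher, 13 lower and 2 did not pass (14 over the list alone, camera adjusted p = 1.1e-06, 0.37 with estimated correlation). Of 10 perivenous hepatocyte genes, 0 were higher, 8 lower and 2 did not pass (8 over the list alone, camera adjusted p = 3.4e-05, 0.37 with estimated correlation). Of 27 peroxisomal beta-oxidation and peroxisome genes, 1 was higher, 17 lower and 9 did not pass (19 over the list alone, camera adjusted p = 1.6e-06, 0.37 with estimated correlation). Of 32 cell cycle genes, 6 were higher, 0 lower and 26 did not pass (3 over the list alone, camera adjusted p = 0.0018, 0.37 with estimated correlation). Fen1 (0.65 ± 0.13), Mcm7 (0.73 ± 0.15) and Stmn1 (0.75 ± 0.20) were among those higher. Of 24 rat liver preneoplasia and tumour markers, 7 were higher, 1 lower and 16 did not pass (9 over the list alone, camera adjusted p = 0.014, 0.37 with estimated correlation). Tff3 (1.01 ± 0.25) and Cd24 (1.58 ± 0.44) rose and Myc (-0.82 ± 0.22) fell. Of 15 macrophage and Kupffer cell markers, 0 were higher, 6 lower and 9 did not pass (6 over the list alone, camera adjusted p = 0.0041, 0.37 with estimated correlation). C1qa (-1.09 ± 0.13) and Clec4f (-2.31 ± 0.35) were lower. Of 12 endothelial cell markers, 0 were higher, 5 lower and 7 did not pass (5 over the list alone, camera adjusted p = 0.035, 0.37 with estimated correlation). Of 5 pancreatic acinar markers, 2 were higher, 0 lower and 3 did not pass (3 over the list alone, camera adjusted p = 0.02, 0.37 with estimated correlation). Of 20 stellate cell and fibroblast markers, 6 were higher, 2 lower and 12 did not pass (8 over the list alone, camera adjusted p = 0.073, 0.43 with estimated correlation). Gstp1 was at -0.66 ± 0.27 and the fetal liver gene Afp at -0.18 ± 0.16, neither past 0.05.

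In the CA arm 15 TU sections of 9 rats, among them rev rat 4151 and rats 4152 and 4156 labelled 18, were compared with their untagged sections. Mmp12 rose by 2.84 ± 0.55 (7.14-fold, adjusted p = 0.031), Slc25a4 by 2.35 ± 0.62, Cdkn2a by 1.15 ± 0.31 and the class II antigen gene RT1-Ba by 1.11 ± 0.23 in 1 of 2 probe sets (0.10 in the other, not past), and Cyp1a2 (-1.87 ± 0.43), Cyp2c7 (-1.81 ± 0.48), Slc2a2 (-1.42 ± 0.37) and Ehhadh (-0.72 ± 0.15) fell. Called probe sets numbered 432 (99 higher, 333 lower), 46 and 67 after quantile normalization, 2501 without rat 4137, 4 without 4141 and 1 without any other single rat. None passed in limma with only the 6 CA rats of 12m and 18m (972 had an unadjusted p below 0.05), and 4 passed with array brightness as a covariate. Of 27 peroxisomal beta-oxidation and peroxisome genes, 0 were higher, 7 lower and 20 did not pass (19 over the list alone, camera adjusted p = 1.5e-09, 0.23 with estimated correlation). Of 21 coagulation and complement genes, 0 were higher, 6 lower and 15 did not pass (17 over the list alone, camera adjusted p = 1.5e-09, 0.23 with estimated correlation). Of 28 urea cycle and amino acid breakdown genes, 0 were higher, 8 lower and 20 did not pass (16 over the list alone, camera adjusted p = 4.9e-09, 0.23 with estimated correlation). Of 25 cytochrome P450 and other phase I genes, 0 were higher, 8 lower and 17 did not pass (19 over the list alone, camera adjusted p = 9e-06, 0.23 with estimated correlation). Of 18 cholesterol synthesis genes, 0 were higher, 7 lower and 11 did not pass (10 over the list alone, camera adjusted p = 1.4e-06, 0.23 with estimated correlation). None of 24 rat liver preneoplasia and tumour markers passed, with a median of 0.13 (2 over the list alone, camera adjusted p = 0.003, 0.23 with estimated correlation). None of 20 stellate cell and fibroblast markers passed, with a median of 0.14 (0 over the list alone, camera adjusted p = 0.003, 0.24 with estimated correlation). Of 7 cholangiocyte markers, 0 were higher, 1 lower and 6 did not pass (4 over the list alone, camera adjusted p = 0.046, 0.34 with estimated correlation). The fold changes of both arms, which shared no rats, had Pearson's r of 0.75 across 8325 genes, which are not independent replicates. Of the genes called in both arms 43 were higher and 214 lower, against 9.24 and 44.6 for independent lists, and none was opposite. No probe set passed for the difference between the arms in limma, and 1812 had an unadjusted p below 0.05 (4 passed without 4109). None of 25 cytochrome P450 and other phase I genes passed (median -0.53, 6 over the list alone, camera adjusted p = 4.2e-06). None of 16 bile acid synthesis and transport genes passed (median -0.51, 5 over the list alone, camera adjusted p = 4.6e-05). None of 16 growth hormone and sex dependent liver genes passed (median -0.67, 6 over the list alone, camera adjusted p = 0.00021). None of 18 cholesterol synthesis genes passed (median 0.49, 8 over the list alone, camera adjusted p = 0.00021). All 4 had a camera adjusted p of 0.46 with estimated correlation. All include rat 4137, which moved against the other CA rats and may cause part of these gaps.

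PERI sections of 5 rats were compared with the untagged and with the TU sections of the same rats, to see on which side they lay. Against untagged sections no probe set passed in limma, 283 had an unadjusted p below 0.05, and Cyp7a1 was at 0.28 ± 0.17 and Ccng1 at -0.11 ± 0.16. None of 16 bile acid synthesis and transport genes passed, with a median of 0.21 (0 over the list alone, camera adjusted p = 0.042, 0.97 with estimated correlation). Without rat 4137 the direction of this list turned (camera adjusted p = 0.34). Against PERI the TU sections were higher in Fabp4, a fatty acid binding protein of adipocytes and macrophages (1.47 ± 0.16, 2.76-fold, adjusted p = 0.026), and in Pttg1, a securin (1.27 ± 0.13). These were the only 2 probe sets, 2595 had an unadjusted p below 0.05, and 1278 passed without rat 4137, 0 without 4104, 4109, 4142 or 4143. None of 25 cytochrome P450 and other phase I genes passed, with a median of -0.41 (16 over the list alone, camera adjusted p = 4.5e-05, 0.65 with estimated correlation). None of 15 growth hormone and sex dependent liver genes passed, with a median of -0.66 (13 over the list alone, camera adjusted p = 3.5e-05, 0.65 with estimated correlation). None of 16 bile acid synthesis and transport genes passed, with a median of -0.62 (11 over the list alone, camera adjusted p = 1.7e-05, 0.65 with estimated correlation).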

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

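The tests of explanations for rats 4137 and 4043 and the arm difference at 3m, with their bounds and errors, the brightness covariate, the exchange of sections and the splits were chosen only after the results were seen, and the other tests were planned. Samples far from their group were searched for in 69 groups of values, and 15 had one. Most were rat 4137, so the groups are not independent.

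In the CA arm, rat 4137 moved against the 8 other rats in TU less untagged sections, with Mmp12 at -3.76 (others 2.3 to 4.72), Slc25a4 at -4.44 (0.12 to 4.57), Cdkn2a at -1.71 (0.59 to 2.14), Cyp1a2 at 2.88 (-3.49 to -1.55), Cyp2c7 at 2.87 (-4.12 to -1), Slc2a2 at 2.45 (-3.22 to -1.08) and Ehhadh at 0.56 (-1.29 to -0.48). Its untagged section had a TU score of 0.19 (others -2.72 to -2.27), which argues against a TU section with little TU tissue as the whole cause, its TU section scored -2.74 (others -1.15 to -0.31) and its PERI section -2.78. A difference in array brightness is argued against by a log2 ratio of array medians of -0.14, inside the range of the other rats (-0.29 to 1.45). Exchanged labels of the untagged and TU sections remain a candidate explanation, as the TU less untagged difference of 4137 correlated with that of the DEN-CA arm at -0.77 across genes, which are not independent replicates, against 0.49 to 0.72 in the other rats. With its sections exchanged, 2999 probe sets passed in the CA arm instead of 432, and no biological explanation was tested.

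In CA rev against control rev, control rev rat 4043 was the highest of 7 rats in 95.8% of the 72 probe sets called lower, and with it left out 7 passed instead of 91. T or NK cells in its section are 1 candidate explanation, with a mean log2 signal of 9.43 for that list (7 to 7.78 in the other rats), 14 of its 16 measured genes highest in 4043 and Prf1 at 3750 against at most 238 in CA rev rats, while Cd3e reached 38.5. Blood in the section is another, with 10.55 for erythroid markers (8.89 to 9.31), and macrophage (10.46, others 9.18 to 9.73), B and plasma cell (10.58, 8.62 to 9.32) and neutrophil markers (7.24, 6.04 to 6.58) were also highest in 4043. No gene belongs to both the T and NK and the erythroid list, and liver holds some cells of each kind. Both explanations stay open, and so does a real difference between the rev groups, where chance was not excluded as 3 of 35 splits of the 7 rats gave as many calls.

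The CA effect at 3m differed between the arms in 27 probe sets, with a median absolute change of 1.06 and a standard error of 0.25. With array brightness as a covariate the change was 0.85 with an error of 0.24, 80.6% of the first value, and 1 probe set passed, as the change became smaller at about the same error. After quantile normalization it was 0.94 with an error of 0.23, 89.1% of the first value, and 20 of the 27 passed, and with the B suffix as a covariate, on 4 of 5 DEN-CA arrays and 1 or 2 in the other groups, it was 0.97 with an error of 0.23, 91.6%, and 2 passed. With jackknife errors over the 20 rats of 13.5%, 16.2% and 19.4%, each share lay more than 1 error above 50%, the bound set for a cause, and none lay that far above 80%, the bound set to exclude one. Array brightness, the shape of the signal distribution and the B suffix may each explain a part, none was shown or excluded, and a different response to CA after DEN stays open as well.

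Other differences between groups, each from a test of the difference itself, were these. The CA effect at 18m less that at 5j had 90 probe sets, with Scd2 at 3.82, Cela1 at 3.00, Cyp1a2 at 2.02, Cyp7a1 at 1.76, Angptl4 at -1.40, Hmox1 at -1.49, Cyp4a8 at -2.48, Acot1 at -2.56, Aldh1a1 at -2.72 and Cd36 at -3.52. CA less CA rev had 181, with Scd2 at 3.98, Vnn1 at 3.66, Acot1 at 3.39, Aqp3 at 3.26, Cxcl12 at -1.92, Oat at -2.77 and Apoa4 at -4.33. DEN-CA less DEN-CA rev had 285, with Acot1 at 3.64, Hdc at 3.52, Scd2 at 3.50, Socs2 at -2.87, Cish at -3.86, Nrep at -4.07, Apoa4 at -4.24 and Obp3 at -5.68. Between arms 5 passed at 5j, with Stat5b at -1.12, and 1 at 9m. At 3m Ssh2 was at 1.38, Chn1 at 1.16, Mink1 at 1.06, Ifnar1 at -0.86, Lman1 at -1.12, Mug1 at -1.34 and Cand2 at -1.55.

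Single rats far from their group were control 4040 for Scd2 at 18m (283, others 22.6 to 34.5) and DEN rat 4077 for Scd2 at 12m (57.4, others 25.6 to 33.9). In TU less untagged sections of the DEN-CA arm they were 4111 for Bex3 (0.35, others 2.69 to 4.44), 4107 for Slc25a4 (2.35, 3.64 to 4.25) and 4109 for Cyp1a2 (-1.64, -4.03 to -3.15) and Slc27a5 (-1.32, -3.29 to -2.53).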

How the results depend on the processing

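The brightness covariate, the covariate for the upper tail of the array, the sets without rats 4040, 4043, 4046 and 4111 and without 4081 and 4084, and the exchange of the sections of 4137 were chosen after the results were seen. Comparisons are named by their treated group, and the arm difference is the CA effect with DEN less that without. The report gave these counts of called probe sets. CA had 1390 at 5j, 1788 at 1m, 1762 at 3m, 840 at 9m, 1444 at 12m, 841 at 18m and DEN 38 at -8, 5 at 5j, 0 at 1m, 1 at 3m, 0 at 9m, 0 at 12m. DEN-CA had 1302 at 5j, 2007 at 1m, 1771 at 3m, 866 at 9m, 872 at 12m and the arm difference 5 at 5j, 0 at 1m, 27 at 3m, 1 at 9m, 0 at 12m. CA at 18m less 5j had 90, CA rev 91, CA less CA rev 181, DEN rev 1, DEN-CA rev 15, DEN-CA less DEN-CA rev 285, CA labelled 18 2881 and ageing 895. TU in the CA arm had 432, TU in the DEN-CA arm 3418, TU between arms 0, PERI 0 and TU against PERI 2.

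The deposited values without scaling gave other counts. CA had 494 (51 higher, 443 lower, against 529 and 861) at 5j, 197 (124 higher, 73 lower, against 722 and 1066) at 1m, 8280 (51 higher, 8229 lower, against 865 and 897) at 3m, 192 (147 higher, 45 lower, against 490 and 350) at 9m, 236 (68 higher, 168 lower, against 816 and 628) at 12m, 175 (104 higher, 71 lower, against 395 and 446) at 18m and DEN 5 (5 higher, 0 lower, against 15 and 23) at -8, 0 at 5j. DEN-CA had 261 (85 higher, the rest lower, against 793 and 509) at 5j, 946 (912 higher, 34 lower, against 1334 and 673) at 1m, 907 (861 higher, 46 lower, against 1222 and 549) at 3m, 252 (225 higher, 27 lower, against 273 and 593) at 9m, 212 (74 higher, 138 lower, against 405 and 467) at 12m and the arm difference 0 at 5j, 9403 (9403 higher, 0 lower, against 18 and 9) at 3m, 0 at 9m. CA at 18m less 5j had 26 (19 higher, 7 lower, against 42 and 48), CA rev 2 (1 higher, 1 lower, against 19 and 72), CA less CA rev 31 (23 higher, 8 lower, against 93 and 88), DEN rev 0, DEN-CA rev 5 (5 higher, 0 lower, against 9 and 6), DEN-CA less DEN-CA rev 123 (15 higher, 108 lower, against 120 and 165), CA labelled 18 1289 (96 higher, 1193 lower, against 1499 and 1382) and ageing 405 (378 higher, 27 lower, against 486 and 409). TU in the CA arm had 427 (413 higher, 14 lower, against 99 and 333), TU in the DEN-CA arm 1450 (366 higher, 1084 lower, against 1338 and 2080), TU between arms 21 and TU against PERI 258 (15 higher, 243 lower, against 2 and 0). The median of all probe sets also moved on the log2 scale. CA stood at -0.33 at 5j, -0.71 at 3m, 0.14 at 9m, -0.17 at 12m and DEN -0.25 at -8, -0.31 at 9m. DEN-CA stood at -0.21 at 5j, 0.31 at 1m, 0.34 at 3m, 0.35 at 9m, -0.18 at 12m and the arm difference 0.34 at 1m, 1.11 at 3m, 0.20 at 9m. CA at 18m less 5j stood at 0.33, DEN-CA rev 0.27, DEN-CA less DEN-CA rev -0.44, CA labelled 18 -0.28 and ageing 0.33. TU in the CA arm stood at 0.28, TU between arms -0.37, PERI 0.36 and TU against PERI -0.36. These counts therefore include differences in array brightness.

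Quantile normalization was tried as well. CA then had 1812 (875 higher, 937 lower, against 529 and 861) at 5j and DEN 37 (24 higher, 13 lower, against 15 and 23) at -8, 9 (4 higher, 5 lower, against 0 and 1) at 3m. DEN-CA then had 2359 (1289 higher, 1070 lower, against 1334 and 673) at 1m, 2106 (1187 higher, 919 lower, against 1222 and 549) at 3m, 1094 (583 higher, 511 lower, against 273 and 593) at 9m and the arm difference 19 (5 higher, 14 lower, against 2 and 3) at 5j, 1 at 1m, 41 at 3m. CA at 18m less 5j then had 161, CA rev 142 (54 higher, 88 lower, against 19 and 72), CA less CA rev 415 and DEN-CA less DEN-CA rev 564 (297 higher, 267 lower, against 120 and 165). TU in the CA arm then had 113 (46 higher, 67 lower, against 99 and 333) and TU in the DEN-CA arm 3656 (1814 higher, 1842 lower, against 1338 and 2080). With only the groups of a contrast in the fit, and so fewer residual degrees of freedom, the counts were CA 748 at 5j, 565 at 3m, 932 at 12m, DEN 11 at -8, 1 at 5j, DEN-CA 854 at 5j, 1232 at 1m, the arm difference 0 at 5j, 1 at 3m, CA at 18m less 5j 39, CA rev 0, CA less CA rev 83, DEN rev 0, DEN-CA rev 5 and ageing 268. A limit of 2-fold besides the adjusted p lowered counts. CA kept 224 at 5j, 280 at 1m, 258 at 3m, 194 at 9m, 240 at 12m, 197 at 18m and DEN 13 at -8, 3 at 5j. DEN-CA kept 253 at 5j, 282 at 1m, 260 at 3m, 171 at 9m, 210 at 12m and the arm difference 2 at 5j, 15 at 3m. CA rev kept 52, DEN rev 0, DEN-CA less DEN-CA rev 177, CA labelled 18 322 and ageing 152. TU in the CA arm kept 81 and TU in the DEN-CA arm 494. With array weights they were CA 1561 at 9m, 1742 at 18m, DEN 150 at -8, 1 at 1m, DEN-CA 1551 at 9m, 1599 at 12m, the arm difference 1 at 5j, 44 at 1m, 14 at 3m, CA at 18m less 5j 161, CA rev 20, CA less CA rev 408, DEN rev 2, DEN-CA rev 34, DEN-CA less DEN-CA rev 823 and CA labelled 18 4483. With the upper tail of the array as a covariate they were CA 1317 at 9m, 1367 at 18m, DEN 5 at 3m, DEN-CA 1453 at 12m, the arm difference 18 at 5j, 1 at 1m, 71 at 3m, 0 at 9m, CA at 18m less 5j 205, CA rev 161, CA less CA rev 490, DEN-CA less DEN-CA rev 621 and ageing 1582.

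With log2 array median as a covariate they were DEN 2 at 3m, the arm difference 1 at 3m and TU in the CA arm 4. The B suffix as a covariate gave DEN 2 at 3m, DEN-CA 1670 at 9m, the arm difference 2 at 3m, 3 at 9m and ageing 1871. Pooling controls and rev controls of the same month gave CA 1375 at 18m, CA rev 239 and DEN rev 0. The 70th percentile filter gave DEN 3 at 5j, the arm difference 8 at 5j, DEN rev 0 and TU against PERI 0. No filter gave the arm difference 1 at 5j, TU in the CA arm 1 and TU against PERI 0. An offset of 6 gave DEN 2 at 3m, DEN rev 0 and TU against PERI 1. An offset of 99 gave the arm difference 8 at 5j, CA rev 166 and DEN rev 3. Leaving out 4040, 4043, 4046 and 4111 gave CA rev 11, CA less CA rev 37, DEN-CA rev 24 and ageing 541. The control rev arm of 18m was then rat 4044 alone, assumed to vary like the other groups.

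Exchanging the sections of 4137 gave TU in the CA arm 2999 and TU against PERI 2158. With all sections and the rat as a random block the counts were DEN 2 at 3m, the arm difference 2 at 5j, 17 at 3m, 0 at 9m, CA less CA rev 111 and DEN rev 0. With each tagged section and the rat as a random block they were TU in the CA arm 874 and TU against PERI 0. Without pairing of sections by rat, the counts were TU in the CA arm 624, TU in the DEN-CA arm 2580, TU between arms 0, PERI 0 and TU against PERI 0.

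With only the CA rats of 12m and 18m, TU in the CA arm gave 0 called probe sets in limma, and without 4115 the arm difference at 9m gave 0.

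Leaving out each rat in turn gave these ranges of counts. CA ran from 1031 to 1368 at 5j, 1421 to 1816 at 1m, 1381 to 1841 at 3m, 606 to 839 at 9m, 979 to 1450 at 12m, 663 to 901 at 18m and DEN 14 to 115 at -8, 3 to 7 at 5j, 0 to 2 at 1m, 1 to 10 at 3m, 0 to 0 at 9m, 0 to 0 at 12m. DEN-CA ran from 964 to 1274 at 5j, 1562 to 2303 at 1m, 1334 to 1826 at 3m, 617 to 772 at 9m, 664 to 810 at 12m and the arm difference 0 to 29 at 5j, 0 to 0 at 1m, 2 to 225 at 3m, 0 to 1 at 9m, 0 to 1 at 12m. CA at 18m less 5j ran from 70 to 135, CA rev 7 to 272, CA less CA rev 88 to 293, DEN rev 0 to 3, DEN-CA rev 11 to 17, DEN-CA less DEN-CA rev 212 to 359, CA labelled 18 2411 to 2812 and ageing 514 to 908. TU in the CA arm ran from 1 to 2501, TU in the DEN-CA arm 2539 to 3302, TU between arms 0 to 4, PERI 0 to 0 and TU against PERI 0 to 1278. For the 188 gene results of the text, 3969 values under alternatives were on the same side of the threshold, 425 fell short of the threshold, 2 passed it newly and 3 changed sign. For the lists these were 2354, 207, 20 and 4. A change of sign was counted only where the value or that of the report passed, so 3969 and 2354 can hold other changes of sign. The sign changes were, in the arm difference at 3m without scaling, Ifnar1 at 0.19, Lman1 at 0.1 and the apolipoprotein list at an adjusted p of 0.79. They were, with quantile normalization the acute phase list at 0.91 and the secreted protein list at 0.72. They were also, without the 4 rats Klrb1a in CA rev at 0.51, with 4044 as the only control (-0.45 without 4043 alone), and for bile acid genes in PERI an adjusted p of 0.34 without 4137 (range 0.00085 to 0.34 over rats left out). Under an estimated correlation between genes 13 list calls were left of 364. The cause was not tested, except where fewer samples or residual degrees of freedom are named. The covariate for RNA quality from 3 prime and 5 prime control probe sets could not be run, since the table used held none of these probe sets. Other counts under the alternatives lay within 1.5 times those of the report. Without pairing by rat only the count of TU against PERI moved by over 1.5 times, and 5 calls of genes ended. The mean signal of dim genes limits what can be seen, since the offset of 25 shrinks their folds.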

Other observations

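The splits were chosen after the results were seen.

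TU sections of rats in the rev groups came from 2 rats, and no comparison held them alone. In DEN-CA rev rat 4111 its 2 TU sections had Scd2 at 557 and 586 against 170 in its untagged section, Cela1 at 1590 and 993 against 238, Acot1 at 93.9 and 44.4 against 5.94, Obp3 at 4.21 and 53.7 against 334 and Apoa4 at 3770 in both against 2660. In untagged DEN-CA rats of 12m Scd2 stood at 1480 ± 332 and Acot1 at 320 ± 61.1. The TU section of CA rev rat 4151 had Apoa4 at 722 against 6150 in its untagged section, Scd2 at 449 against 64.6 and Cela1 at 968 against 235. With 1 rat in each case these are values without a test.

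Pancreatic genes were high in 1 TU section of DEN-CA rev rat 4111, with Prss1 at 4050 and 56.9 in the other TU section of that rat. Obp3 was near background in 18m control rat 4040 (11.3) and ranged up to 3540 in that group. Rat 4115 was labelled 9m although its number lies among those of later groups.

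Labels were exchanged among the rats of each comparison in 100 splits, the real one included, or in all where fewer exist, and the number of called probe sets was compared. Many of these splits keep part of the contrast, as the highest other split of CA against control at 5j, which exchanged 1 CA rat for control 4010, so the highest other counts are not counts without an effect. For CA against control chance was excluded, as no other split reached the real count, with the highest other at 621 for 1390 (5j), 1239 for 1788 (1m), 1667 for 1762 (3m), 257 for 840 (9m), 498 for 1444 (12m) and 431 for 841 (18m), so 1 of 100 splits in each case. It was also excluded for DEN-CA against DEN, with 676 for 1302 (5j), 821 for 1771 (3m), 111 for 866 (9m) and 164 for 872 (12m), 1 of 100 each. At 1m 2 of 100 splits gave as many as the real 2007, and the highest other gave 2546. Chance was excluded for CA labelled 18 (2881, highest other 1144), for ageing (895, 254) and for DEN against control at -8 (38, 30), each with 1 of 100, and for TU in the DEN-CA arm (3418, 1664), with 1 of 64. For TU in the CA arm 3 of 100 gave as many as 432, the highest 1394, and both of the others had rat 4137 turned against most rats. Chance was left open for the CA effect at 18m less 5j (90, highest 397, 4 of 100). The same holds for DEN-CA less DEN-CA rev (285, 490, 2) and the arm difference at 3m (27, 885, 2). Here time or arm was redrawn within treated and within untreated rats, so main effects can enter. The 397 and 885 point to a structure among the rats.

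Chance was not excluded for DEN against control at 5j (5, highest 298, 10 of 100), 1m (0, 1275, 100), 3m (1, 669, 35), 9m (0, 1, 100) and 12m (0, 2, 100). The split with 1275 at 1m set all 5 arrays without the B suffix against all 5 with it, and splits with far more calls than the real one again point to a structure of the samples. Nor was it for the arm difference at 5j (5, 321, 14), 1m (0, 2408, 100), 9m (1, 2, 5) and 12m (0, 1, 100), for CA rev (91, 155, 3 of 35), CA less CA rev (181, 659, 8 of 100), DEN rev (1, 130, 20), DEN-CA rev (15, 118, 13) and TU between arms (0, 20, 100). For PERI (0, highest 0) and TU against PERI (2, highest 0) there were 16 splits, too few for a share under 0.05.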
